A study of Homo sapiens with 12 samples.

How the data were processed

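Gene expression was measured by RNA sequencing of cardiomyocytes derived from RUES2 human embryonic stem cells on 2 scaffolds, 8% PVA and 9.75% PEDOT:PSS/PVA, after 3 days of culture from day 50. Cells were detached with trypsin, RNA was extracted with QIAzol and a column, and libraries were made from ribodepleted total RNA, per the labels' protocols. Ribodepleted total RNA keeps transcripts without a poly(A) tail and unspliced RNA, so histone and noncoding genes are measured too. The deposited table holds raw counts of read pairs per gene name in 12 libraries, not normalized by the authors, per the file headers. Counting was done with featureCounts 2.0.1 in paired-end mode with the reversely stranded setting on GENCODE release 33, summed by gene name, per the file headers. No option for multi-mapping or multi-overlapping reads stands in that command, so reads that match several places or genes were left out, which lowers counts of near-identical paralogs. The submitters' processing notes name FastQC, STAR, featureCounts, DESeq2, edgeR and the build hg38; the aligner's version and options are not given in the sources used here. Coordinates are those of the deposited table on hg38.

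The table lists 60583 gene names, and every row names a gene. Library totals were 19.1 to 30.96 M counts, and 27495 to 30138 genes had a count in a library. Gene types and older symbols were looked up in a RefSeq gene table of assembly GRCh38.p14, used for names only. Of 916 symbols in the gene lists, all 916 were matched, 2 of them through a synonym.

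The labels give 3 biological replicates per scaffold with 2 technical libraries each. What separates technical libraries (a second scaffold, extraction or library preparation) is not stated in the labels. Their counts differed by more than sampling noise, so they were not the same library deposited again. The biological replicate was taken as the unit, and the technical libraries were summed to 6 sums, 3 against 3. Where biological replicates are not stated to be separate differentiations, p-values measure only the spread between these samples. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 21298. Counts were scaled with TMM and tested in edgeR 4.0.16 under R 4.3.3 (glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg over the genes tested, threshold 0.05) with the scaffold as the only term. A standard error of a gene is the log2 fold change divided by the square root of the test's F statistic. Levels are CPM, scaled to the library total and the TMM factors, and log2 CPM used a prior count of 2.

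Replicate numbers are shared between the scaffolds, so a fit with the replicate number as a block was fixed as an alternative before the data were examined. Deviations of same-numbered sums from their scaffold means correlated at 0.678, 0.703 and 0.503 across genes, and those of sums with different numbers at -0.609 to -0.005. By the rule set for this (every pair over 0.1) the numbers pair the samples. The pairing comes from the values, since no label states that a number marks a shared culture or day. Paired values are therefore printed wherever they change a call. A count of genes from the fit with the block is called the paired count: 57 against 0.

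The design, 44 gene lists of contractile, electrical, metabolic, stress and cell type genes, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested genes (42) were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. At the preset correlation 9 lists were called, 3 higher and 6 lower, and with an estimated correlation or fry 0 were. The named genes are, first, those past the threshold with a mean CPM of 5 or more, a symbol and 3 PEDOT sums all above or all below the 3 PVA sums, 10 per direction, or, where fewer than 5 passed, the 5 of smallest p as uncalled values. Next come up to 3 members of smallest p in each list, and a fixed panel of 12 maturation genes. Some results under these rules are withheld and left out of the text. For calls of the paired fit, the same direction in the 3 pairs took the place of separated scaffolds, a choice made after the data were examined. OAS1, OAS3, GBP2, GBP4, HERC6, PAEP's values per sum and GAP43 were chosen after their values were seen. Isoform shares were compared by an exact permutation test over the 20 assignments of the 6 sums, two-sided.

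The procedure was tested on simulated counts drawn from the fitted means and dispersions of the 21298 genes with 200 genes changed. Without the block, 1 of 67 genes with a 1.5-fold change, 23 of 67 with a 2-fold change and 61 of 66 with a 4-fold change were recovered, with 9 false calls. These counts were drawn independently for each sum, with no effect shared by same-numbered sums. The real sums are paired by number, so these figures do not describe the real fit without the block. With the block, 45 of 67, 63 of 67 and 66 of 66 were recovered, with 18 false calls. The planted list was called in both, and 0 of 41 other lists were, but simulated genes vary independently, which real genes do not. Alternatives were DESeq2 1.42.0, limma-voom, other scaling and filters, the 12 libraries with and without an estimated correlation, 1 technical library per replicate, removal of mitochondrial and ribosomal RNA genes, a fold threshold of 1.2, and leaving out each replicate or library in turn. Without the block, leaving out 1 replicate kept its same-numbered partner on the other scaffold, so the replicate numbers were then unbalanced. The same alternatives around the fit with the block were added after the data were examined. There, whole pairs rather than single replicates were left out. List medians within a pair in the closing tests are means over libraries and were set against the differences between technical libraries or the spread of list members. There, the SE of a list is the SD of its members over the root of their number. It treats the members as independent and does not measure spread between cultures. These tests, and their bounds, were chosen after the results were seen.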

Results

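The series asked whether an electrically conductive fibre scaffold changes gene expression in human stem cell-derived cardiomyocytes, with function and maturation as its stated theme. RUES2 is an established human embryonic stem cell line. Its cardiomyocyte derivatives were placed at day 50 on electrospun scaffolds for 3 days. The control scaffold was 8% polyvinyl alcohol (PVA), which does not conduct. The conductive scaffold was 9.75% PEDOT:PSS/PVA, in which the conducting polymer blend PEDOT:PSS is combined with PVA, and it is called PEDOT here. Ribodepleted total RNA was sequenced from 3 biological replicates per scaffold, each with 2 technical libraries, which gave 12 libraries. Library totals were 19.1 to 30.96 M assigned counts with a median of 24.1 M, and the 6 sums of technical libraries held 44.5 to 57.5 M.

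The replicate number, rather than the scaffold, separated the samples. On the 6 sums, replicate number accounted for 74.7% of the variance in log2 CPM (library-scaled counts), the scaffold for 9.55%, and 15.7% was left. Sums with the same number on the 2 scaffolds correlated at r = 0.991 to 0.993 across genes, and replicates of 1 scaffold at 0.969 to 0.985. Technical libraries of 1 replicate correlated at 0.988 to 0.991, but their counts differed by more than sampling noise, with a chi-square per gene of 6.67 to 16.96. The largest of these belonged to PVA replicate 3, whose libraries 1 and 3 also differed in several of the genes described below. Mitochondrially encoded genes took 4.00 to 5.48% of counts on PVA and 3.98 to 5.198% on PEDOT.

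**Figure D1:**
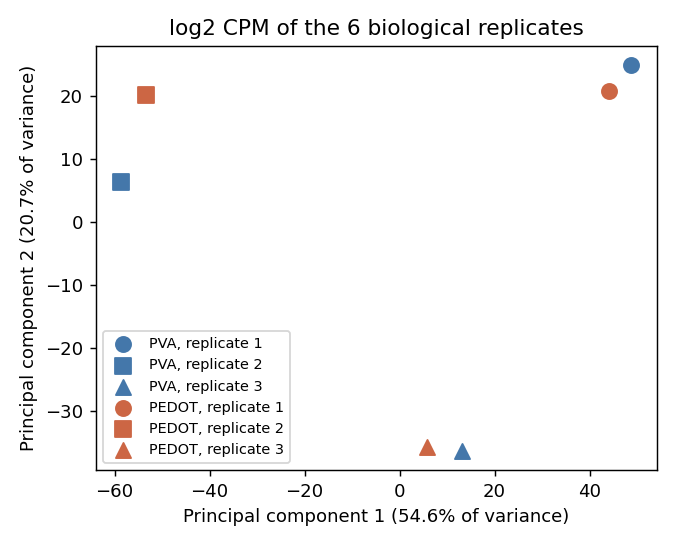
First and second principal components of log2 CPM for the 6 biological replicates (technical libraries summed), with colour for the scaffold and marker shape for the replicate number. The components hold 54.6% and 20.7% of the variance, and sums with the same replicate number lie next to each other on both scaffolds.

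The comparison of PEDOT with PVA gave no gene past the threshold when the replicate number was not in the model. When same-numbered replicates were paired, the interferon response list had the most members called lower on PEDOT among the tested lists, at 9. With an estimated correlation the list was not called (paired camera adjusted p 0.858). MYH7, the slow beta myosin heavy chain of the adult human ventricle, was among the genes called higher with pairing. MYH6, the alpha heavy chain, was at the same level on both scaffolds. Without the block, 0 of 21298 genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05, DESeq2 and limma-voom also called 0, and 190 genes had an unadjusted p under 0.05, which is 0.892% of those tested. The 3 PEDOT sums lay all above or all below the 3 PVA sums in 4.597% of genes. Both shares are lower than the 0.05 and 0.1 of genes that independent sums would give without a scaffold effect. The 0 calls therefore do not show that the scaffolds are alike. With the replicate block, 57 genes passed, 15 higher and 42 lower on PEDOT, and 1771 genes had an unadjusted p under 0.05. The direction of all 57 was the same in the 3 pairs, while 5 of them had scaffolds that did not overlap. The same 3 pairs gave the calls, so the shared direction is no separate support for them. The paired count depended on the filter, the scaling and single libraries: it was 1 gene when only genes with a mean CPM of 5 or more were kept and 389 when every gene with a count was kept.

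Among genes that encode the contractile apparatus, MYH7 (chromosome 14, 23412740 to 23435660, hg38) averaged 614.03 ± 355.58 CPM on PVA and 1130.3 ± 402.2 CPM on PEDOT (SD, n = 3). Its log2 fold change was 0.88 ± 0.44 (SE) without the block, with an edgeR adjusted p of 0.99999. In the paired edgeR fit it was 0.95 ± 0.17, a 1.94-fold higher level with an adjusted p of 0.038, and MYH7 was higher on PEDOT in 3 of 3 pairs. The log2 differences within the pairs were 1.71, 0.86 and 0.30. The paired call was kept in 8 of 16 other settings. Those that kept it include both fits of the 12 libraries, where technical libraries add to the replicates. Also among them are the fits with every gene with a count and without pair 3, whose prior degrees of freedom were infinite. Tallies of other genes below are drawn from the same settings. It was lost, at log2 fold changes of 0.85 to 1.08, with DESeq2 (adjusted p 0.99994), upper-quartile scaling (0.205), library size only (0.0928), a mean CPM of 5 or more (0.283), the lower-numbered (0.0592) or higher-numbered (0.233) technical libraries alone, a fold threshold of 1.2 (0.302) and without pair 2 (0.312). Leaving out single libraries ended it in 8 of 12 cases (MYH7 adjusted p 0.0542 to 0.193). MYH6 (chromosome 14, 23381982 to 23408273), which lies next to MYH7 and is similar in sequence, averaged 18623 ± 3224 CPM on PVA and 18356 ± 2738.8 CPM on PEDOT (SD, n = 3), a log2 fold change of -0.02 ± 0.22 (SE).

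The share of MYH7 in the summed MYH7 and MYH6 counts, a measure of the fetal-to-adult myosin switch in the human ventricle, was 3.23 ± 1.77% on PVA and 6.01 ± 2.74% on PEDOT (SD, n = 3). It was higher on PEDOT in 3 of 3 pairs, but a two-sided exact permutation test gave p = 0.2 where the smallest possible p is 0.1 for n = 3. TNNI3, the adult cardiac troponin I, made up 1.91 ± 0.71% of TNNI3 plus TNNI1 counts on PVA and 2.17 ± 0.48% on PEDOT (exact p = 0.7, n = 3). MYL2, the ventricular regulatory light chain, made up 13.8 ± 6.83% of MYL2 plus MYL7 counts on PVA and 15.1 ± 8.74% on PEDOT (exact p = 0.8, n = 3). Adjusted over the 3 shares, the exact p-values were 0.6, 0.8 and 0.8. In PVA replicate 3 the MYH7 share was 3.75% in library 1 and 7.10% in library 3, so technical libraries of 1 replicate differed by more than the mean difference between scaffolds.

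The ventricular sarcomere list, which holds 23 structural and contractile genes, was called higher by camera at its preset correlation (adjusted p 0.00224), with 21 members above 0 and a median log2 fold change of 0.15. Its adjusted p was 0.873 with an estimated correlation. In the paired fit 1 member, MYH7, passed over all genes and 4 were higher when adjusted over the list alone. MYL2 was at a paired log2 fold change of 0.45 ± 0.13 (SE, edgeR adjusted p 0.256) and TCAP, the titin cap at the Z-disc, at 0.56 ± 0.14 (0.154), and neither passed. Leaving out PVA replicate 1 turned the median to -0.05 (adjusted p 0.909), and leaving out PEDOT replicate 2 lowered it to 0.04 (0.167). These fits had no block, so the same-numbered sum of the other scaffold stayed in without its partner. With the block and a whole pair left out, the camera adjusted p was 0.122 without pair 1. It was 9.72e-04 without pair 2 and 9.71e-05 without pair 3. The list's medians within the pairs were 0.28, 0.09 and 0.06.

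The lists of calcium handling, ion channel, intercalated disc, fatty acid oxidation, respiratory chain and fetal contractile genes did not pass. The calcium handling list had a median log2 fold change of 0.07, with 17 of 22 members above 0 (camera adjusted p 0.250). RYR2, the calcium release channel of the sarcoplasmic reticulum, averaged 1794.9 ± 216.27 CPM on PVA and 2084.9 ± 319.64 CPM on PEDOT, and ATP2A2, which encodes the SERCA2 calcium pump, 4558.6 ± 922.28 and 4728.9 ± 683.69 CPM (SD, n = 3). The ion channel list had a median of 0.04 over 28 genes (adjusted p 0.442), with CACNA1C, the L-type calcium channel, at a log2 fold change of 0.13 ± 0.10 (SE) and KCNJ2, which carries the inward rectifier current, at -0.12 ± 0.39. The intercalated disc list was at 0.03 over 23 genes (adjusted p 0.583), and its member GJA1, which encodes connexin 43, was at 0.25 ± 0.22 (SE). Fatty acid oxidation genes were at -0.004 over 33 genes (adjusted p 0.949), nuclear-encoded respiratory chain genes at -0.02 over 46 (0.815) and the fetal contractile list at -0.04 over 13 (0.994). In the paired fit 1 fetal contractile gene, ACTA2, was called lower and 12 were not called. Leaving out PVA replicate 1 brought the fatty acid oxidation list past the threshold with a median of -0.13. Leaving out PVA replicate 3 brought calcium handling past it at 0.12 and ion channels at 0.10. These fits had no block, so the same-numbered PEDOT sum stayed in without its partner. Within the pairs the fatty acid oxidation medians were 0.11, -0.11 and -0.01. They were 0.16, 0.005 and 0.02 for calcium handling and 0.12, -0.01 and -0.01 for ion channels. None was called in the paired fit (camera adjusted p 0.939, 0.111 and 0.286).

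All 28 tested members of the interferon response list, the genes that type I interferon induces, had a log2 fold change below 0, and the list's median was -0.43 (camera adjusted p 1.0397e-12, and adjusted p = 0.873 with an estimated correlation). In the paired fit the median was -0.39, 9 members were called lower over all genes, and 26 of 28 were lower when adjusted over the list alone. MX1, an antiviral GTPase, averaged 21.87 ± 18.68 CPM on PVA and 4.49 ± 2.22 CPM on PEDOT (SD, n = 3), a paired log2 fold change of -2.02 ± 0.23 (SE, edgeR adjusted p 0.00289). OAS1, OAS2 and OAS3, which sense double-stranded RNA, had paired log2 fold changes of -2.74, -2.44 and -1.91. Their levels were low, at means of 3.89, 2.52 and 5.63 CPM on PVA and 0.54, 0.42 and 1.33 CPM on PEDOT. In pair 2, where OAS1 was at 0.30 and 0.15 CPM, their log2 differences were only -0.85, -0.56 and -1.08. ISG15, a ubiquitin-like modifier, averaged 19.64 ± 7.86 CPM on PVA and 11.22 ± 2.03 CPM on PEDOT (edgeR paired adjusted p 0.0382). IFI44 and RSAD2 were also called lower, at -1.11 and -1.06. The list's medians within the pairs were -0.76, -0.28 and -0.25.

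The level on PVA was uneven between libraries. MX1 was at 42.4 and 38.3 CPM in the libraries of PVA replicate 1, at 4.67 and 2.51 CPM in those of PVA replicate 2, and at 33.3 CPM in library 1 but 7.66 CPM in library 3 of PVA replicate 3. On PEDOT, MX1 was between 1.93 and 7.15 CPM in the 6 libraries. Without PVA replicate 3 library 1, the paired fit called 2 interferon list members lower and 36 genes in all, and the list's paired median was -0.32. It called 2 members without PEDOT replicate 1 library 3, and 0 with upper-quartile scaling, at a mean CPM of 5 or more and with the higher-numbered technical libraries alone. The median without the block was between -0.64 and -0.24 when each biological replicate was left out, and the list stayed past the camera threshold each time. It was -0.26 at a mean CPM of 5 or more, where the interferon response list was still called.

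**Figure D2:**
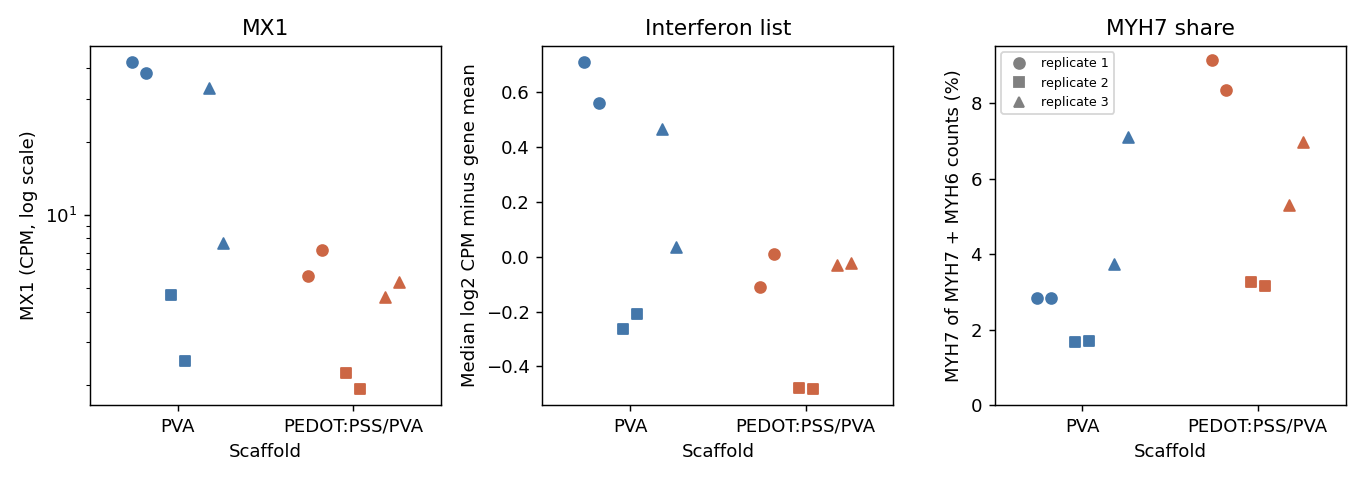
MX1 in CPM on a log axis (left), the median over the 28 interferon list genes of log2 CPM minus each gene's mean over the 12 libraries (middle), and the MYH7 percentage of MYH7 plus MYH6 counts (right), with 1 point per library, colour and position for the scaffold and marker shape for the replicate number. PVA replicate 1 and 1 library of PVA replicate 3 hold the highest MX1 levels, at 33.3 CPM or more, and the MYH7 share runs from 1.68 to 9.14%.

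Genes of cell division were lower on PEDOT in replicate pair 1 above all. The cell cycle list had 34 of 36 members below 0 and a median log2 fold change of -0.22 (camera adjusted p 4.5391e-06, and adjusted p = 0.873 with an estimated correlation), and no member passed over all genes in either fit. Within the pairs its median was -1.03, -0.11 and 0.09, and leaving out PEDOT replicate 1 turned it to 0.03 (adjusted p 0.951). RRM2, a subunit of ribonucleotide reductase, had a log2 fold change of -0.55 ± 0.42 (SE), and BIRC5, which encodes survivin, -0.40 ± 0.35. Histone genes, whose transcripts mostly lack a poly(A) tail and peak in S phase, had 21 of 22 members below 0 with a median of -0.18 (camera adjusted p 1.4378e-04, and adjusted p = 0.873 with an estimated correlation), and were at -0.46, -0.12 and -0.01 in the pairs. Without PEDOT replicate 1 the histone list's call was lost, with a median of -0.05. Fibroblast markers such as DCN and LUM had a median of 0.83, 0.06 and 0.11 in the pairs. They were not called without the block (camera adjusted p 0.442), were called higher with it (0.0145), and were at 0.858 as an adjusted p with an estimated correlation.

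Hypoxia response genes had a median log2 fold change of 0.21 with 21 of 22 members above 0 (camera adjusted p 7.951e-05), and glycolysis genes 0.09 with 23 of 25 above 0 (0.00964). Both had an adjusted p of 0.873 with an estimated correlation. DDIT4, a stress-induced inhibitor of mTORC1, was at a log2 fold change of 0.56 ± 0.31 (SE), PDK1, the pyruvate dehydrogenase kinase, at 0.32 ± 0.16, and ENO2, an enolase, at 0.35 ± 0.20, and none passed edgeR's test. The hypoxia medians within the pairs were 0.16, 0.55 and 0.08, and the glycolysis medians 0.04, 0.32 and -0.01. Technical libraries of 1 replicate differed in the hypoxia list's median by up to 0.75, more than the scaffolds did. Without PVA replicate 2 both calls were lost, with medians of 0.06 and 0.01, and without PEDOT replicate 1 they were lost at 0.09 and 0.08. Leaving out PEDOT replicate 2 or PEDOT replicate 3 also ended the glycolysis call, at 0.10 and 0.09. Single libraries ended the hypoxia call too: PEDOT replicate 1 library 3 (median 0.09, adjusted p 0.107), PVA replicate 3 library 3 (0.11, 0.109) and PEDOT replicate 3 library 1 (0.14, 0.304), each left out alone. Both calls were lost with the lower-numbered technical libraries alone, at 0.09 for hypoxia and 0.05 for glycolysis. Leaving out single libraries ended the glycolysis call in 6 of 12 cases, at medians of 0.03 to 0.07, and it was lost with every gene with a count, at 0.10.

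Stress and clearance lists were slightly lower on PEDOT, most of all in pair 2. The NRF2 list, which holds antioxidant genes, had a median log2 fold change of -0.11 over 26 genes (camera adjusted p 0.00714), the heat shock list -0.09 over 21 (0.00714), and the lysosome and autophagy list -0.07 over 28 (0.00224), each with an adjusted p of 0.873 with an estimated correlation. Within the pairs the NRF2 medians were -0.07, -0.23 and -0.02, and those of lysosome and autophagy -0.08, -0.18 and -0.03. Heat shock was higher in pair 1, with medians of 0.07, -0.24 and -0.09. NQO1, a quinone reductase, averaged 9.31 ± 0.63 CPM on PVA and 6.87 ± 1.32 CPM on PEDOT (SD, n = 3), and the chaperone HSPA1A 13.99 ± 0.56 and 11.18 ± 0.36 CPM. CTSB, the lysosomal protease cathepsin B, was called lower in the paired fit at -0.45 ± 0.07 (SE, edgeR adjusted p 0.0200). Without PVA replicate 2 the calls of all 3 lists were lost, with medians of -0.04, 0.003 and -0.05, and leaving out PEDOT replicate 3 ended those of NRF2 at -0.11 and heat shock at -0.04. All 3 calls were also lost with the higher-numbered technical libraries alone (medians -0.10, -0.06 and -0.03) and with every gene with a count (-0.11, -0.09 and -0.07). The heat shock call was lost without PVA replicate 3 library 1, at -0.07. With the block, 15 lists were called in place of 9, and inflammation, matrix metalloproteinases and metallothioneins joined the lower ones at medians of -0.13, -0.10 and -0.42. Matrix collagens at 0.09 and skeletal muscle genes at 0.21 joined the higher ones, as did fibroblast markers at 0.30. Within the pairs, matrix collagens were at 0.37, -0.01 and -0.004 and matrix metalloproteinases at 0.06, -0.17 and -0.33. The medians of the inflammation, metallothionein and skeletal muscle lists kept their direction in every pair. All 15 were lost with an estimated correlation, where the smallest adjusted p was 0.858.

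**Figure D3:**
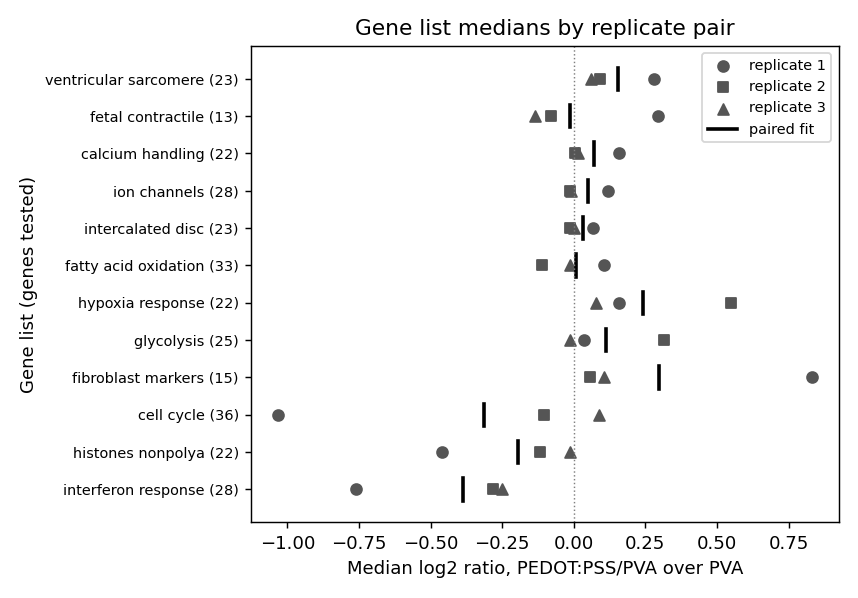
Median log2 ratio of PEDOT to PVA for 12 fixed gene lists, with 1 marker per replicate pair and a bar for the paired fit. The interferon response list is below 0 in the 3 pairs (-0.76, -0.28 and -0.25), while the cell cycle list runs from -1.03 to 0.09.

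Of the 57 genes called in the paired fit, 15 belonged to a fixed list and 42 to none. Besides MYH7, the largest higher calls among named genes with a mean CPM of 5 or more were GPC3, a heparan sulfate proteoglycan, at a paired log2 fold change of 0.67 ± 0.11 (SE), the matrix protein gene TNXB at 0.67 ± 0.12, GLP1R, the receptor of glucagon-like peptide 1, at 0.61 ± 0.11, LINC01182 at 0.47 ± 0.08, RRAD at 0.44 ± 0.07, GABRE at 0.41 ± 0.06, VIPR2, a receptor of vasoactive intestinal peptide, at 0.41 ± 0.07, AQP1, a water channel, at 0.40 ± 0.08 and NR4A1, an immediate early transcription factor, at 0.38 ± 0.07. RRAD encodes a small GTPase that inhibits L-type calcium channels, and without the block it was the gene of smallest p among the separated genes named here. It averaged 27.28 ± 1.01 CPM on PVA and 36.96 ± 1.47 CPM on PEDOT (SD, n = 3), with an edgeR adjusted p of 0.99999 without the block and 0.0272 with it. Single libraries overlapped, with RRAD at 19.2 to 36.2 CPM on PVA, both in replicate 3, and at 25.3 to 49.1 CPM on PEDOT, both in replicate 1, and its paired call was kept in 8 of 16 other settings. FGF12 and SRPX also had separated scaffolds, with unadjusted p-values of 0.0175 and 0.0197 in edgeR without the block and no call in either fit.

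The largest lower calls outside the interferon list at a mean CPM of 5 or more were the chemokine gene CCL21 at a paired log2 fold change of -1.14 ± 0.14 (SE), the secreted lipocalin PAEP at -0.89 ± 0.09, the receptor tyrosine kinase RET at -0.85 ± 0.13, PROCR, the endothelial protein C receptor, at -0.79 ± 0.12, PHOX2A, a transcription factor of autonomic neurons, at -0.79 ± 0.13, and the neurotrophin receptor gene NGFR at -0.74 ± 0.13. Their levels varied several-fold between replicates: PAEP was at 97.54, 3.68 and 6.25 CPM in the PVA sums and at 52.2, 1.98 and 3.40 CPM in the PEDOT sums of the same numbers. The smooth muscle genes ACTA2, which is also on the fetal contractile list, and RGS5 were called lower in the paired fit, at -0.40 ± 0.07 and -0.46 ± 0.06. The smooth muscle list as a whole did not pass (camera adjusted p 0.311 without the block and 0.121 with it). UBE2L6, the conjugating enzyme of ISG15, and GBP1, an interferon-induced GTPase, were called lower with the block at -0.48 ± 0.09 and -0.52 ± 0.08. Interferon-induced GBP2, GBP4 and HERC6 were also called lower with the block, at -0.50 ± 0.07, -0.55 ± 0.09 and -0.50 ± 0.09. The 9 calls of the interferon list thus do not hold every interferon-induced gene among the 57. KDR and LDOC1 had edgeR unadjusted p-values of 0.0176 and 0.0198 without the block and were called in neither fit.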

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

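The tests in this part were chosen after the results were seen. In 38 library measures on each scaffold (76 sets of 6 libraries), 1 value lay apart from the rest: PEDOT replicate 1 library 3 had a total of 30.2 M counts, while the other 5 PEDOT libraries had 22.9 to 24.1 M. No chance rate was determined for this rule, and the measures are not independent. With 76 sets examined, this value is given without a reading.

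Splits of the samples bear on the counts of lists and of paired calls. The 6 sums make 10 splits of 3 against 3 and, with pairs kept, 4 exchanges of scaffolds within pairs, too few for a share under 0.05. Without the block the real split gave 0 genes and the highest of the others 1 gene; that all 10 splits gave as many follows from the 0 and tests nothing. The real split gave 9 lists and the highest other 23, and 9 of the 10 splits gave 9 lists or more. Among the splits that part all 3 pairs, as the real one does, the highest other gave 14 lists. With the block, the real assignment gave 57 genes and the other exchanges 0, so 1 of 4 gave as many. The real assignment gave 15 lists and the highest other 21, and 4 of 4 gave as many. A list call at the preset correlation was thus no rarer in the other splits and exchanges than in the real one. These do not ignore the scaffold fully, since the exchanges keep some pairs in their real direction. They can hold part of a scaffold effect, and do not show how many lists would be called without one.

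Interferon response genes were lower on PEDOT in each pair: their medians in pair 1, pair 2 and pair 3 were -0.74, -0.26 and -0.23 log2 as means over libraries. An SE given here is taken over the list's members in 1 pair, not over cultures. Fewer endothelial cells on PEDOT are argued against in pair 1, where the 13 endothelial markers had a median of 0.455 (SE 0.157), but stay open in pair 2, where they were lower like the interferon genes, at -0.285 (SE 0.120), and in pair 3 at 0.0298 (SE 0.154), so that the paired median of -0.0301 averages opposite pairs. The pattern may rest on PVA replicate 1 and library 1 of PVA replicate 3. Pair 2, which holds none of these libraries, argues against them as the only source. There, 27 of 28 members were lower, with a median of -0.259 (SE 0.0609) against differences of 0.0451 and 0.0385 between its technical libraries. The technical libraries of PVA replicate 3 differed by 0.484, however, so a drop of the size in pair 2 can arise between libraries of 1 replicate. In pair 3 the explanation by these libraries stays open, since without PVA library 1 the median was -0.0941 (SE 0.0736) with 19 of 28 members lower. An effect of the scaffold and a difference between single cultures stay open, since pair 2 has 1 sum per scaffold.

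MYH7 was higher on PEDOT in the paired fit, at 0.95 log2, with MYH6 level. A larger share of cardiomyocytes would raise their other contractile genes alike, but the other 22 ventricular sarcomere genes had a paired median of 0.15 (bootstrap interval over genes 0.08 to 0.21). MYH6 reads counted as MYH7 would give the same MYH7 share in every library, and the highest share, 9.14%, was 5.45 times the lowest, 1.68%. These values argue against both as the whole cause. An effect of the scaffold on ventricular myosin remains a hypothesis, since MYH7 was called only with the block and lost that call at a similar fold with DESeq2 (0.95 log2, adjusted p 0.99994).

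Cell cycle genes were lower on PEDOT in pair 1, at a median of -1.05 log2 with 36 of 36 members below 0, and not in pair 3, at 0.08. No single technical library carried this, since the 4 combinations of PVA and PEDOT libraries of replicate 1 gave medians of -0.69 or lower, while technical libraries of 1 replicate differed by up to 0.322. Fewer fibroblast-like cells on PEDOT are argued against by the fibroblast markers, which had a median of 0.83 in pair 1 with 13 of 15 members above 0. Fewer dividing cells of another type, and a difference between cultures unrelated to the scaffold, stay open, since 1 pair cannot tell them apart from an effect of PEDOT.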

How the results depend on the processing

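The alternatives around the fit with the replicate block were chosen after the data were examined, and the others before. Without the block, the count of genes stayed at 0 under every scaling, filter, test and left-out replicate or library. The block gave 57 genes (15 higher, 42 lower) and 15 lists in place of 9, and it changed no other call beyond those printed with the results. Without the block no named gene had a call to lose. Of 3685 values set against that fit, 3572 stayed uncalled with the same direction and 56 changed sign uncalled. The other 57 were called, all through adding the block. Of 903 paired values, 554 kept their call and 349 lost it. For called lists outside the primary ones 216 of 248 were kept, 30 lost their call and 2 reversed, and 340 of 403 paired were kept. The cause was not tested for any change listed here unless a value shows it. The list count was 5 with every gene with a count, 0 with an estimated correlation and 0 by fry, and 7 to 17 over left-out replicates and libraries.

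Paired counts of genes (higher, lower) were 1 (0, 1) with upper-quartile factors, 37 (8, 29) with library size only, 96 (29, 67) with DESeq2, 389 (187, 202) with every gene with a count and 1 (0, 1) at a mean CPM of 5 or more. They were 194 (71, 123) with 12 libraries as replicates, 173 (63, 110) with a correlation estimated within replicates, 16 (3, 13) with the lower-numbered and 4 (4, 0) with the higher-numbered technical libraries, and 8 (0, 8) at a fold threshold of 1.2. Leaving out a pair or a library gave 4 to 284 genes (0 to 140 higher, 4 to 144 lower) and 12 to 17 lists. The prior degrees of freedom behind these counts were 11.96 as reported, 7.33 with upper-quartile factors and 5.42 at a mean CPM of 5 or more. They were 31.4 without pair 1 (170 genes), and infinite without pair 3 (284 genes) and with every gene with a count. In these fits of summed libraries the larger counts came with the larger values. The order broke with 12 libraries as replicates (8.87) and with the higher-numbered libraries (9.72), fits that differ in the number of libraries or in depth. The cause was not tested. Paired lists were 0 with an estimated correlation and 0 by fry.

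Values in this paragraph are list medians unless named otherwise. Calcium handling was called at a mean CPM of 5 or more (median 0.0887, camera adjusted p 0.00846) and with a correlation within replicates (median 0.0809, camera adjusted p 0.00375). With 12 libraries, which counts technical libraries as replicates, it was called at a median of 0.0774 (camera adjusted p 0.0496). Fatty acid oxidation moved to 0.0155 with upper-quartile factors, 0.00905 with limma-voom, 0.00334 at a mean CPM of 5 or more, 0.00551 with a correlation within replicates, 0.00729 with the higher-numbered libraries and 0.00829 with the block. It was called in none of these settings. The fetal contractile list moved to 0.00659 with a correlation within replicates and 0.0223 with the higher-numbered libraries, and ion channels to -0.0365 with the lower-numbered ones, not called. Over left-out replicates and libraries the medians were -0.0465 to 0.277 for the ventricular sarcomere list, -0.107 to 0.137 for fetal contractile, -0.0251 to 0.126 for calcium handling, -0.0351 to 0.103 for ion channels, -0.0344 to 0.0437 for the intercalated disc, -0.132 to 0.0980 for fatty acid oxidation, -0.719 to 0.0261 for cell cycle and -0.145 to 0.00323 for heat shock. The direction turned for ventricular sarcomere without PVA replicate 1 (-0.0465), heat shock without PVA replicate 2 (0.00323) and cell cycle without PEDOT replicate 1 (0.0261). These fits had no block and kept the same-numbered sum of the other scaffold. The share difference was 0.871 for TNNI3 per kilobase, and over left-out replicates 1.44 to 4.18 for MYH7, -0.146 to 0.516 for TNNI3 and -3.36 to 5.28 for MYL2.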

Other observations

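The tests and genes in this part were chosen after the data were examined. GAP43, a growth cone protein called lower in the paired fit, was at 3.75 ± 1.43 CPM on PVA and 1.98 ± 0.52 CPM on PEDOT (SD, n = 3), a paired log2 fold change of -0.89 ± 0.17 (SE, edgeR adjusted p 0.0444), a call kept in 7 of 15 other settings. The fixed neural list had 9 of 11 members below 0 in the paired fit with a median of -0.27, and it did not pass camera (adjusted p 0.0941). STMN2, a neuronal tubulin regulator, was at -0.47 ± 0.12 with an edgeR adjusted p of 0.174.

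Several cell type lists were not called in the paired fit, and some moved in opposite directions between pairs. Endothelial markers had a paired median of -0.03 (camera adjusted p 0.790) with 0.58, -0.56 and 0.02 in the pairs, and endoderm markers -0.22 (0.261) with -0.01, 0.04 and -0.89. Epicardial markers were at -0.08 (0.782), atrial genes 0.06 (0.233), nodal genes 0.06 (0.273), ventricular genes 0.07 (0.261) and cardiac transcription factors 0.03 (0.378). Fibroblast markers differed far more between replicate numbers than between scaffolds: LUM averaged 16.13 ± 12.32 CPM on PVA and 28.21 ± 27.34 CPM on PEDOT (SD, n = 3).

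Among the lists without a call in either fit, genes encoded by mitochondrial DNA had a paired median of -0.07, the TCA cycle -0.01, ribosomal proteins -0.02, housekeeping genes -0.04, the unfolded protein response -0.02, p53 targets -0.04, cholesterol synthesis -0.03, TGF-beta targets -0.02, immediate early genes -0.005, adhesion genes -0.06, nuclear noncoding RNAs -0.02 and growth factor and receptor genes 0.06.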
